A study of Mus musculus with 8 samples.

How the data were processed

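RNA of mouse embryonic stem (ES) cells was amplified with biotin labelling and hybridised to 8 Illumina expression arrays, per the labels' protocols. The cells were of the R1 line and lacked Fgf4. They had been kept overnight in serum-free N2B27 medium with BMP4 at 10 ng/ml and were then cultured to day 3 with FGF4 at 20 ng/ml, with LIF at 10 u/ml or with no growth factor. Each sample carried 1 shRNA vector. The labels give 4 groups of 2 arrays: FGF4 with the Mp1 shRNAs shMp1Lib and shMP1G, and the control shRNAs shRnd1 and shRnd2 with FGF4, with LIF and with no growth factor. A title gives each sample's shRNA, which serves as its replicate number. The treatment note in the labels gives the Rnd1 shRNA for both LIF samples, while their titles give shRnd1 and shRnd2. The titles were followed, so the shRNA of the LIF array named shRnd2, and with it the replicate number there, is in doubt. The labels do not say that the arrays of a group came from separate cultures.

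The deposited non-normalized table holds, for 45281 probes and each array, an intensity on a linear scale and a detection p-value, per the file headers. The scanner software, its settings and the tools that made the processed values are not given in the sources used here. In 294271 of the 362248 intensity cells (81.2%) the deposited number had lost its decimal point, and 67977 cells were intact. The point was put back from the number of digits. For 207073 cells whose digits allowed 2 readings, and for whole numbers with fewer digits, the detection p-value of the same cell was used as well. An intensity near background has a detection p-value above 0 and a bright one has 0. The lowest intact intensity with a detection p-value of 0 was 109.55. After this step, 0 of the restored cells had a detection p-value more than 0.1 outside the order given by the intact cells. The Spearman correlation of intensity and detection p-value across probes lay between -0.990 and -0.982 on each array (probes are not independent replicates). Both checks are in part built in, because detection p-values chose the reading of many cells. The rule was tested on simulated signals before use. No per-sample column was left out for lack of a sample (0 columns).

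A second deposited table, the series' value table, holds intensity values of 42293 probes on the same arrays, with column medians of 82.6 and 82.5 for the Mp1 shRNAs, 82.4 and 82.5 for the control shRNAs with FGF4, 82.5 and 82.5 with LIF, and 82.6 and 82.6 with no growth factor. Of its 6529 rows with a mean above 256, 5746 matched exactly 1 row of the restored table by their profile over the 8 arrays (distance of at most 0.05 in log2 units after quantile normalization), so its values are linear, quantile normalized between arrays and not centred by gene. Of those matches, 0 carried the same probe ID in both tables, and the correlation of log2 values of one ID between the tables was 0.126 to 0.177 across probes. The IDs were therefore judged by genes of known abundance. In the non-normalized values 82 probes of ribosomal proteins had a median percentile of 99.5 and 1287 probes of olfactory receptors one of 21.8, against 57.1 and 43.5 in the value table under its own IDs. Proteasome subunits (66 probes) lay at 91.6 against 61.4 and keratin-associated proteins (52 probes) at 19.4 against 42.2. The non-normalized table was used for all named results, and the value table only without names, as an alternative. Why the IDs differ stays unknown.

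Gene symbols come from the platform annotation of the probes listed in the value table. Of the 45281 probes, 32245 had 1 symbol, 17 had several and were left unnamed, and 13019 had none here. Of the named probes, 32170 had a gene ID in the RefSeq gene table of assembly GRCm38.p6, used for names only, which changed 0 symbols. The value table leaves out 2988 probes of the non-normalized table, which are unnamed here. Coordinates were not used.

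Intensities were processed with limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) by neqc: normexp background correction with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p-value under 0.05 on at least 2 of the 8 arrays were kept. Of several probes with one symbol, the probe with the highest mean over all arrays was taken. This left 14103 features, of which 8933 were named. Where another probe of a named gene that passed lay in the opposite direction, it is given. A model of 4 group means over all 8 arrays was fitted with lmFit and eBayes (4 residual degrees of freedom and 4.18 of the prior), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. All adjusted p-values of single genes are from limma's moderated test. All 6 comparisons between groups were made.

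Normalized log2 intensities are given as mean ± SD. A gene whose probe was detected on no array of a group is called not well above background there. Its fold is then given as at least N-fold: the brighter group's mean log2 value against the mean of, per array, the higher of the lowest value among detected probes and the probe's own value.

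In all 6 comparisons the named genes were the 10 largest rises and 10 largest falls among named genes past the threshold, the 5 smallest p-values in a direction where under 5 genes passed, and up to 4 members of each of 22 gene lists, those with the smallest p. The lists (naive pluripotency, general pluripotency, formative and primed epiblast, neural ectoderm, primitive streak and mesoderm, endoderm, trophoblast, surface ectoderm and simple epithelium, FGF/ERK feedback and early response, LIF/STAT3 targets, BMP/SMAD targets, MP1 complex and MAPK core, p53 targets, interferon response, lysosome, cholesterol synthesis, glycolysis, cell cycle, Hox genes, germline, epithelial to mesenchymal, and fibroblast feeder markers), the groups, tests, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise. Lists were tested against the other features with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. A call lost with an estimated correlation does not by itself show that members vary together. Genes in several lists count in each (Klf4 in naive pluripotency and LIF/STAT3 targets, Dppa3 in naive pluripotency and germline, Gata3 in trophoblast and BMP/SMAD targets, Msx1 in surface ectoderm and BMP/SMAD targets, Gata2 in primitive streak and BMP/SMAD targets, Junb in FGF/ERK and LIF/STAT3 targets).

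The part of the FGF4 response kept under Mp1 knockdown was measured on arrays other than those that chose the features: features at least 2-fold apart between the FGF4 and the no-factor array of one control shRNA were taken, and both differences were then measured against the arrays of the other control shRNA. Overlaps between comparisons that share control arrays are given with the mean of 100 simulations of unchanged groups.

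The test was run on simulated data for FGF4 against no growth factor, with 200 of 14103 features changed. Each feature had its moderated residual SD, pooled over the 4 groups and equal on all arrays, whereas the measured groups varied unequally. At a change of 1 log2 unit the test recovered 0 and at 2 log2 units 197 (98.5%), with 9 false calls. With so few changed features the adjusted threshold is stricter than where many change: in the measured comparison 1451 of 2205 calls were at least 2-fold and the others smaller.

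Alternatives were a replicate block, no background correction, normexp with an offset of 50, scaling by array medians only, the deposited value table, no detection filter, detection on all 8 arrays, all probes singly, a fit of only the 4 arrays compared, eBayes with trend and robust, array weights, leaving out each array (a group left with 1 array was assumed to vary like the others), and selection at 1.5-fold and 3-fold for the response kept. Restricting the tests to named or to listed features, and the arrays labelled LIF as the baseline for the response kept, were added after seeing the data.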

Results

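ES cells lacking Fgf4, which cannot make the autocrine factor that moves ES cells towards differentiation through ERK signalling, were profiled at day 3 on 8 Illumina arrays. With FGF4 supplied at 20 ng/ml, 2 arrays carried shRNAs against Mp1 (shMp1Lib and shMP1G) and 2 carried control shRNAs (shRnd1 and shRnd2). Control shRNA cells were also cultured with LIF at 10 u/ml (2 arrays) and with no growth factor (2 arrays). Mp1, the Lamtor3 gene product, is a scaffold for MEK1 and ERK1 on late endosomes, and the series addresses its part in ES cell differentiation. Between 15375 and 17813 of the 45281 probes were detected per array, the highest number on the shMp1Lib array. The small number of arrays limits the precision of every value, and p-values measure only the spread between these samples, which may be technical. That spread was unequal: the residual SD was 0.310 log2 units for the Mp1 shRNAs, 0.207 for LIF, 0.151 for control shRNAs with FGF4 and 0.130 for no growth factor. Of the features tested, 28.5% differed by over 1.5-fold between the Mp1 shRNA arrays, against 3.96% to 12.2% between the arrays of the other groups.

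The knockdown target could not be measured. The only named Lamtor3 probe was not well above background on any array: its intensity was 71.2 and 63.0 with shMp1Lib and shMP1G, 68.8 and 69.4 with the control shRNAs in FGF4, 63.8 and 64.3 with LIF and 70.2 and 64.8 with no growth factor, with detection p-values of 0.57 or more. These values do not check the labels. The deletion of Fgf4 was not checked either, because 0 probes were named Fgf4. Other subunits of the Lamtor complex were detected on all arrays. Lamtor4 had an intensity of 1419 with shMp1Lib, 4040 with shMP1G, and 5612 and 3873 with the control shRNAs in FGF4. The brightest Lamtor2 probe read 624, 2260, 2114 and 1249 in the same order, and Lamtor1 read 1012, 1374, 1725 and 1441. These are intensities before normalization, and with Mp1 against control shRNAs Lamtor4, Lamtor2 and Lamtor1 did not pass (adjusted p = 0.355, 0.593 and 0.347). The low readings lie on the shMp1Lib array, where respiratory chain and mitochondrial ribosomal protein genes were also lower than with shMP1G (medians of -1.57 and -0.98 log2 units).

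The response of the Fgf4-deficient cells to FGF4 was measured in control shRNA cells against the arrays with no growth factor. Which arrays those are rests on the labels alone, and Socs3, a target of LIF signalling, was higher on them (11.03) than on the arrays labelled LIF (7.65). Car4, a membrane-bound carbonic anhydrase, rose from a level not well above background (4.59 ± 0.12, n = 2) to 11.94 ± 0.03 (n = 2), at least 87.8-fold (adjusted p = 6.12e-06). Esrp1, an epithelial splicing regulator, rose at least 25.2-fold to 10.14 ± 0.03, and the iron exporter gene Slc40a1 at least 25.7-fold to 10.17 ± 0.05. Pou3f1, a POU-domain factor of the epiblast, rose from 6.38 ± 0.06 to 10.78 ± 0.06 (adjusted p = 2.56e-05), and Dusp4, a phosphatase that acts on ERK, rose at least 17.95-fold to 9.65 ± 0.08. In the other direction Spic, an Ets-family transcription factor gene, fell at least 16.2-fold, from 9.48 ± 0.04 to 4.80 ± 0.03, where it was not well above background (adjusted p = 6.12e-06), and the receptor gene Kit fell from 10.07 ± 0.15 to 6.90 ± 0.00. The chemokine gene Cxcl12 rose by 4.43, the tight junction gene Cldn6 by 4.21, the retinol-binding protein gene Rbp7 by 4.36 and Emb by 3.80 log2 units. Gsc, a homeobox gene of the organizer, fell by 3.82 (detected on 1 of 2 FGF4 arrays), Pga5 by 3.62, the sulfotransferase gene Chst3 fell by 3.49 (detected on 1 of 2 FGF4 arrays), Lrrc15 fell by 3.27 and the X-linked homeobox gene Rhox6 by 3.03 log2 units.

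**Figure D1:**
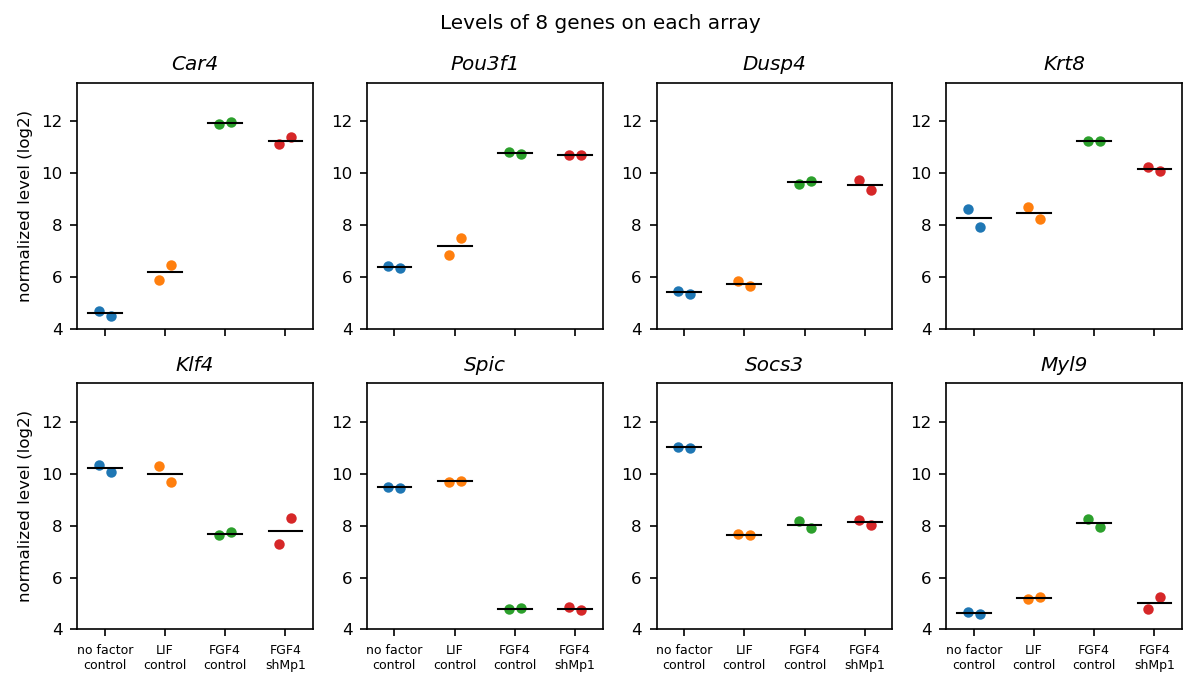
Normalized log2 intensity (y axis) of 8 named genes in the 4 groups, with each array as a point and the group mean as a bar. Car4, Pou3f1 and Dusp4 lie high on the 4 FGF4 arrays, Spic low on them, Socs3 highest on the arrays with no growth factor (11.03), and Myl9 highest on the arrays with FGF4 and control shRNA (8.11).

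Pluripotency genes moved in different directions with FGF4. Of 8 measured genes of naive pluripotency, 6 fell, 0 rose and 2 did not pass, and 7 fell when adjusted over the list alone: Klf4 fell by 2.52, Tbx3 by 1.93, Dppa3 by 1.69 and Klf2 by 1.59 log2 units. The list fell as a set (camera, adjusted p = 1.44e-05; adjusted p = 0.0699 with an estimated correlation). Of 9 genes of the formative and primed epiblast, 7 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone. Beside Car4, Cldn6 and Pou3f1, the de novo methyltransferase gene Dnmt3b rose by 2.96 (detected on 1 of 2 arrays with no factor), and the list rose as a set (adjusted p = 3.73e-09; adjusted p = 0.065 with an estimated correlation). General pluripotency genes divided into 5 that rose, 1 that fell and 6 that did not pass, with 5 and 1 adjusted over the list alone. Dppa4 rose by 1.25, Utf1 by 1.62 and Lefty1, a Nodal antagonist, from 7.92 ± 0.19 to 9.42 ± 0.36, and the list was higher as a set (adjusted p = 0.0257; adjusted p = 0.118 with an estimated correlation, and 0.0704 against named features only). Germline genes gave 1 rise (Taf7l, 1.69), 2 falls (Kit and Dppa3) and 7 that did not pass, with 1 and 2 adjusted over the list alone (camera, adjusted p = 0.321).

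Epithelial and lineage genes followed. Of 13 genes of surface ectoderm and simple epithelium, 8 rose, 2 fell and 3 did not pass, with 9 and 2 adjusted over the list alone. The homeobox gene Msx1 rose by 3.28 to 9.81 ± 0.16, the keratin gene Krt8 by 2.96 to 11.25 ± 0.01 and Tfap2a by 2.38, while Grhl3, an epidermal transcription factor gene, fell by 2.59 (detected on 1 of 2 FGF4 arrays). The list rose as a set (adjusted p = 9.98e-05; adjusted p = 0.0699 with an estimated correlation). In the epithelial to mesenchymal list 6 of 11 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.00734; adjusted p = 0.11 with an estimated correlation). Its rises were of both kinds: the epithelial genes Esrp1 and Cldn3 (at least 4.77-fold), the integrin gene Itgb5 (1.79) and the matrix protease gene Mmp2 (1.49). Of 6 neural genes, Sox11 (at least 8.83-fold) and Map2 (1.31, detected on 1 of 2 arrays with no factor) rose, Ncam1 fell at least 1.595-fold to a level not well above background and 3 did not pass, with 3 and 1 adjusted over the list alone (adjusted p = 0.191). Of 6 primitive streak genes, Evx1 (3.37) and Wnt3 (at least 1.68-fold, not well above background with no factor) rose, Gsc and Gata2 fell and 2 did not pass, with 2 and 2 adjusted over the list alone (adjusted p = 0.45). The rise of Wnt3 did not pass without the shRnd2 array with FGF4 (adjusted p = 0.0998) or without shRnd1 or shRnd2 with no factor (0.105 and 0.106).

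Trophoblast genes gave 1 rise (Ascl2, at least 3.07-fold, not well above background with no factor), 3 falls and 6 that did not pass, with 4 and 4 adjusted over the list alone. Rhox6 fell by 3.03 and Rhox9 by 2.91 log2 units. The median of that list was 0.32 but its mean was -0.45, and camera placed it down (adjusted p = 0.86). Endoderm genes gave 2 rises, 3 falls and 6 that did not pass, with 3 and 3 adjusted over the list alone (adjusted p = 0.97), among them Dab2 (at least 3.22-fold higher, not well above background with no factor) and the collagen IV gene Col4a2, which fell by 1.94. Of 7 Hox genes, 4 fell (4 adjusted over the list alone) and 3 did not pass, and Hoxa7 fell at least 2.04-fold to a level not well above background (list adjusted p = 0.00734; adjusted p = 0.118 with an estimated correlation). Of 6 fibroblast markers, which report on feeder cells, 1 rose (Ccn2, 0.81), 2 when adjusted over the list alone, and 5 did not pass (list adjusted p = 0.191). Ccn2 did not pass without any 1 of the control shRNA arrays (adjusted p = 0.0599 to 0.235).

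Signalling targets also differed. Of 17 genes of FGF/ERK feedback and early response, 9 rose, 2 fell and 6 did not pass, with 10 and 3 adjusted over the list alone. Beside Dusp4, the Ets-family gene Etv4 rose by 2.26 and Bhlhe40 by 2.07, whereas the immediate-early gene Egr1 fell by 1.82 (list adjusted p = 0.00111; adjusted p = 0.0745 with an estimated correlation). Of 9 LIF/STAT3 targets, 3 fell, 0 rose and 6 did not pass, with 2 rises and 5 falls adjusted over the list alone. The cytokine signalling inhibitor gene Socs3 fell by 2.99, Klf4 by 2.52 and Bcl3 at least 4.25-fold to a level not well above background (adjusted p = 0.00966; adjusted p = 0.118 with an estimated correlation). Of 9 BMP/SMAD targets, 4 rose, 1 fell and 4 did not pass, with 5 and 1 adjusted over the list alone. Id3 rose by 2.37 and Id1 by 2.16, and Gata2 fell by 1.55 (adjusted p = 0.0257; adjusted p = 0.118 with an estimated correlation, 0.0673 against named features only, and 0.063 without the shRnd1 array with FGF4). Of 13 interferon response genes, 7 rose, 2 fell and 4 did not pass, with 8 and 3 adjusted over the list alone. The immunoproteasome gene Psmb8 rose by 3.36 to 8.91 ± 0.25, the peptide transporter gene Tap1 at least 4.06-fold and Oasl2 at least 3.19-fold, while Ifi27 fell by 1.53 (adjusted p = 0.00734; adjusted p = 0.118 with an estimated correlation).

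Of 17 p53 targets, 3 rose and 14 did not pass, with 3 adjusted over the list alone (adjusted p = 0.00387; adjusted p = 0.278 with an estimated correlation). The pro-apoptotic gene Pmaip1 rose at least 2.60-fold. Cholesterol synthesis gave 5 rises of 12, 0 falls and 7 that did not pass, with 6 adjusted over the list alone (adjusted p = 0.00023; adjusted p = 0.0699 with an estimated correlation). Its rises were small: 1.08 for Ebp, 0.98 for Dhcr7 and 0.75 for Mvd, each of which did not pass without the shRnd1 or shRnd2 array with FGF4 or with no factor (lowest to highest adjusted p 0.0946 to 0.106, 0.0767 to 0.145 and 0.091 to 0.154). Glycolysis gave 5 rises of 15, 1 fall and 9 that did not pass, with 6 and 1 adjusted over the list alone. Eno3 rose by 1.76 and Hk1 fell by 1.37 (adjusted p = 0.00734; adjusted p = 0.11 with an estimated correlation). Lysosome genes gave 2 rises, 1 fall and 19 that did not pass, with 2 and 1 adjusted over the list alone (adjusted p = 0.182). Among them Ctsa rose by 0.99 but its other probe stood at -0.84, and the rise did not pass without the shRnd1 array with FGF4 (0.0751) or without shRnd1 or shRnd2 with no factor (0.064 and 0.0705). The MP1 complex and MAPK core list gave 1 rise (Rragb, 0.93) and 11 that did not pass, with 1 and 1 adjusted over the list alone (adjusted p = 0.809). Rragb did not pass without the shRnd1 or shRnd2 array with FGF4 (0.131 and 0.194) or without shRnd1 with no factor (0.244). The list median of 0.01 turned to -0.0032 when arrays were scaled by their medians. Of 13 cell cycle genes, 0 passed with limma, over all features or adjusted over the list alone (list adjusted p = 0.97).

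**Figure D2:**
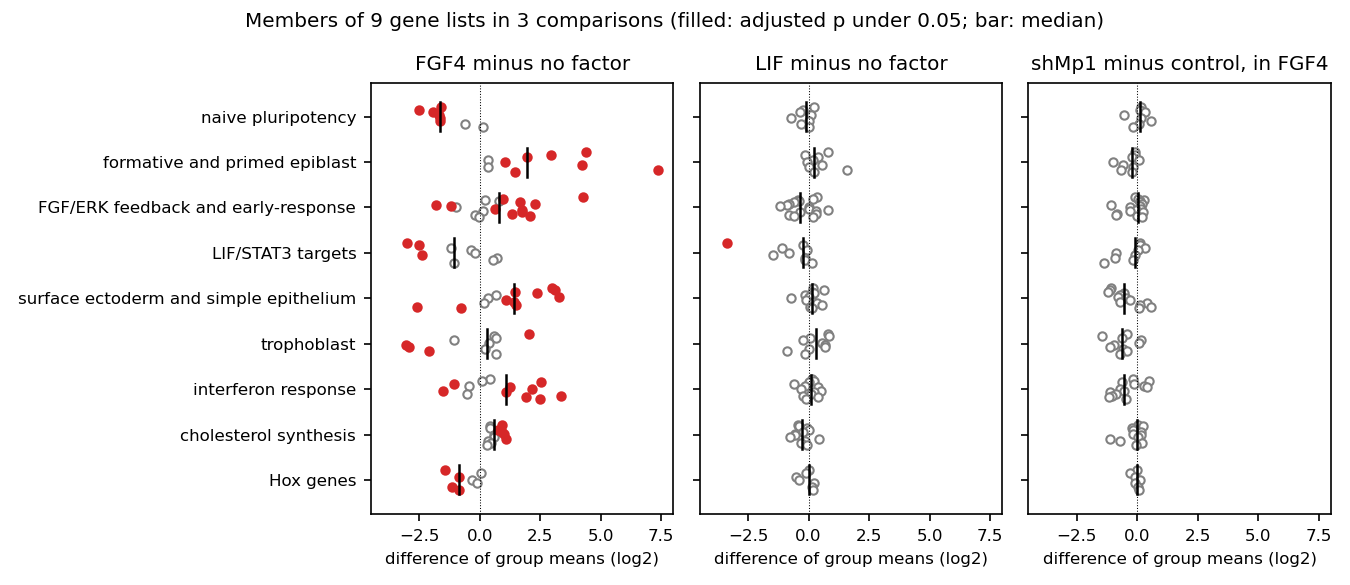
Log2 differences (x axis) of the measured members of 9 gene lists in 3 comparisons: FGF4 against no growth factor, LIF against no growth factor, and Mp1 against control shRNA in FGF4. Each point is a gene, filled where its adjusted p was under 0.05, and bars are list medians; in the Mp1 comparison 0 list members are filled.

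In all, 1106 features rose and 1099 fell with FGF4 (of 14103, with 3919 at an unadjusted p under 0.05), and 734 and 717 of them changed by at least 2-fold. Of the falls 443 were of probes not in the deposited value table, and so unnamed, against 97 of the rises. The named genes and lists of this comparison thus lack more falls than rises. The count of 2205 was 1123 and 1089 without the shRnd1 and shRnd2 arrays with FGF4 and 1030 and 1008 without those with no growth factor. Of the 82 genes past the threshold that the rule for naming genes picks out here, 61 passed whichever array was left out.

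Mp1 knockdown was compared with control shRNAs, both in FGF4, to ask what depends on Mp1 in the response. Myl9, a regulatory light chain of myosin, fell at least 6.76-fold, from 8.11 ± 0.22 (n = 2) with control shRNAs to 5.02 ± 0.33 (n = 2), not well above background, with Mp1 shRNAs (adjusted p = 0.00572). The chemokine gene Cxcl16 fell from 7.65 ± 0.21 to 6.09 ± 0.20 (adjusted p = 0.0389), and Gap43, which encodes a growth cone protein, from 7.67 ± 0.11 to 6.33 ± 0.03 (adjusted p = 0.0389). In all 9 features rose and 5 fell, against 2027 features (14.4%) at an unadjusted p under 0.05. The 9 rises were all of probes without a name here. The probe ILMN_1254295, chosen after its values were seen, rose from 6.55 ± 0.27 to 8.99 ± 0.17 (adjusted p = 0.00955) and read 11.42 and 11.49 on the arrays with no growth factor. Not all of the 9 moved towards that group. ILMN_1249766 rose from 7.64 to 9.79 and read 7.84 and 7.79 there, and ILMN_1213609 rose from 11.57 to 12.98 and read 11.79 and 11.78. A fit with only 1 of the Mp1 arrays takes its spread from the control groups. Their residual SDs were 0.130 to 0.207, against 0.310 for the Mp1 shRNAs. Counts from such a fit may therefore rest on too small a spread. Without shMp1Lib 28 features passed, without shMP1G 2841, without either control array in FGF4 or either array with no growth factor 0, and without either LIF array 2. Myl9 did not pass without the shRnd1 or shRnd2 array in FGF4 (adjusted p = 0.0877 and 0.0897) or without either array with no factor (0.0522), Cxcl16 in 7 of 8 such fits (0.0536 to 0.517), and Gap43 without any control array (0.118 to 0.541). With only the 4 arrays compared, Myl9, Cxcl16 and Gap43 did not pass (0.376, 0.582 and 0.582), and Cxcl16 and Gap43 did not pass without background correction (0.0576 each), with array medians (0.0802 and 0.0596) or with array weights (0.163 and 0.187).

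Named genes just short of the threshold were lower with Mp1 shRNAs: the cell cycle inhibitor gene Sfn by -1.68 (adjusted p = 0.0553), the matrix protein gene Ccn1 by -1.31 (0.0626), Gata3 by -1.47 (0.0729), Egr1 by -1.08 (0.0946) and Krt19 at least 1.51-fold (0.0946), to a level not well above background. On the shMp1Lib and shMP1G arrays Sfn read 6.34 and 6.62, and Ccn1 read 6.54 and 6.38. Values above the control were small for named genes, 0.58 for the ubiquitin ligase gene Trim25 and at least 1.24-fold for Tshz3 (not well above background with control shRNAs), and did not pass (0.226 and 0.234). Of 1660 features at least 0.5 log2 units higher with Mp1 shRNAs, only 73 had a name, since 94.7% of them were not in the deposited value table that gives the names. The named genes and lists of this comparison therefore hold few features higher by at least 0.5 log2 units. Comparisons with Mp1 arrays elsewhere share this limit. Features lower with FGF4 and control shRNAs also often lacked names. Of 1099 falls with FGF4 against no growth factor 443 were not in the value table, against 97 of 1106 rises. With FGF4 against LIF it was 353 of 1088 falls and 111 of 1124 rises.

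**Figure D3:**
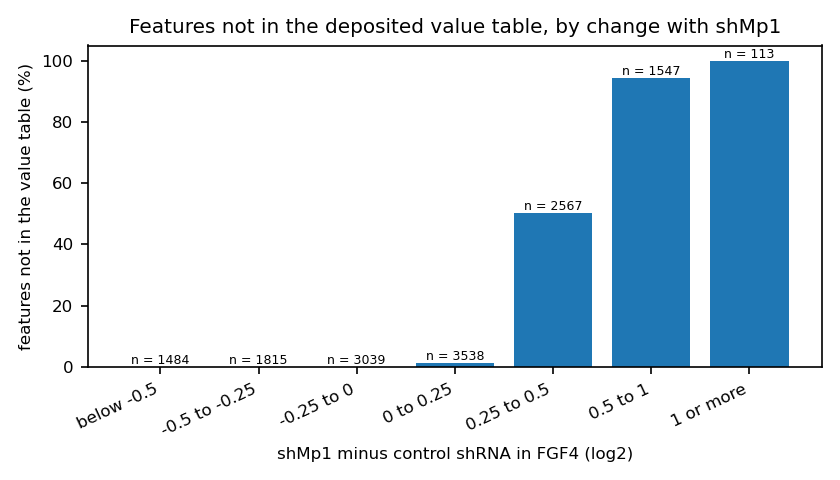
Percentage of tested features not in the deposited value table (y axis), by their log2 difference between Mp1 and control shRNAs in FGF4 (x axis, bins). The percentage is 100 at differences of 1 or more, 94.3 from 0.5 to 1, 50.3 from 0.25 to 0.5, 1.2 from 0 to 0.25 and at most 0.1 below 0.

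Among the gene lists, 0 members passed over all features with limma, and camera placed 5 lists down. Trophoblast genes (10 measured) had 0 rises and 4 falls adjusted over the list alone, including Gata3, Rhox6 (at least 1.23-fold lower, not well above background with Mp1 shRNAs) and Rhox9 (-1.13), and a list adjusted p of 0.000219. Surface ectoderm (13 measured) had 1 and 6, including Krt8 (-1.08) and Krt19 (list adjusted p = 0.00285). Interferon response (13 measured) had 0 and 4, including Ifi35 (at least 2.08-fold lower, not well above background with Mp1 shRNAs) and Psmb8 (-1.03; list adjusted p = 0.00403). The formative and primed epiblast list (9 measured) had 0 and 2, Wnt8a (at least 1.31-fold lower, not well above background with Mp1 shRNAs) and Cldn6 (-0.60; list adjusted p = 0.0119), and BMP/SMAD targets (9 measured) 0 and 2, Gata3 and Msx1 (-0.79; list adjusted p = 0.0167). For all 5 the adjusted p was 0.174 with an estimated correlation, and all 5 calls were lost without shMP1G (adjusted p = 0.117, 0.113, 0.145, 0.117 and 0.0711 for formative, trophoblast, surface ectoderm, BMP/SMAD and interferon), BMP/SMAD also without the shRnd1 array with FGF4 (0.0862). With camera against named features only, the calls of formative genes (adjusted p = 0.0537) and BMP/SMAD targets (0.0786) were lost, and those of trophoblast (0.000832), surface ectoderm (0.0232) and interferon genes (0.0333) were not. This does not remove the unequal naming, since the features clearly higher with Mp1 shRNAs mostly lack names in lists and background alike. The downward calls therefore rest on members left after most such rises were lost.

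Naive pluripotency genes did not pass in this comparison: of 8 measured, 6 were higher and 2 lower, with 0 past when adjusted over the list alone (list adjusted p = 0.81). Of the list's 24 members, 10 had no named probe, so a rise of these with Mp1 shRNAs would not be seen. Tbx3 stood at 9.46 ± 0.27 with Mp1 shRNAs and 9.14 ± 0.12 with control shRNAs, and Dppa3 at 5.15 ± 0.15 (not well above background) and 5.72 ± 0.35. FGF/ERK genes had 0 rises and 3 falls adjusted over the list alone, Egr1, Jun (-0.85, detected on 1 of 2 Mp1 arrays) and Junb (-0.89), with a list median of 0.03, a mean of -0.13 and a list adjusted p of 0.474. Of 12 genes of the MP1 complex and MAPK core, 0 passed (0.474). The arrays with the Mp1 shRNAs differed from each other in housekeeping genes: the median log2 difference of shMp1Lib from shMP1G was -1.57 for 65 respiratory chain genes (62 lower), -0.98 for 70 mitochondrial ribosomal protein genes (55 lower) and -0.31 for 52 cytosolic ribosomal protein genes (39 lower; -0.79 when arrays were scaled by their medians).

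How much of the FGF4 response remained with Mp1 shRNAs was measured on control arrays other than those that chose the features. The labels do not say that these arrays came from separate cultures. A shift shared by both FGF4 control arrays could lower the shares without an effect of Mp1. Of features at least 2-fold higher with FGF4 on shRnd1 (817), the median difference on the shRnd2 arrays was 1.38 with control shRNA and 1.19 with Mp1 shRNAs, so 86.2% remained (shares of 0.845 and 0.894 with shMp1Lib and shMP1G alone). Of features at least 2-fold lower (794), medians were -1.41 and -1.10, and 78.2% remained (0.785 and 0.795). With the control shRNAs exchanged, 86.1% (898 features higher) and 80.8% (886 features lower) remained. Against the arrays labelled LIF, a baseline tried after seeing the data, 95.7% (1147 features higher) and 84.3% (923 lower) remained for features chosen on shRnd1, and 85.1% (798) and 85.3% (815) for those chosen on shRnd2. These shares are medians over features, with no test of their difference from the full response. With the deposited values, an alternative given below, features higher with FGF4 had shares above the full response. Against the control cells, the changes seen with the Mp1 shRNAs correlated across features with the FGF4 response at r = -0.351, where unchanged groups that share the FGF4 control arrays gave -0.50 in simulations. The covariance was -0.104 against -0.0346 simulated, a difference of -0.0689 (features are not independent replicates). The simulations held no FGF4 response, so -0.50 is no baseline for the measured correlation. They also gave all arrays the same spread, while the shared FGF4 control arrays varied less (residual SD 0.151, against 0.310 for the Mp1 shRNAs). The simulated covariance may therefore be too large in size. Between the Mp1 shRNAs, each set against a different control array, the changes correlated at r = 0.0819 across features, and at 0.418 with the control arrays exchanged.

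Mp1 knockdown in FGF4 was also compared with no growth factor. Car4 rose at least 54.6-fold to 11.26 ± 0.19 (n = 2; adjusted p = 5.71e-06), Esrp1 at least 28.3-fold to 10.31 ± 0.42, Slc40a1 at least 22.5-fold to 9.98 ± 0.55 and Dusp4 at least 16.6-fold to 9.53 ± 0.27, and Pou3f1 rose from 6.38 ± 0.06 to 10.69 ± 0.00. Spic fell at least 17.5-fold to 4.80 ± 0.09, not well above background, Rhox6 at least 10.04-fold, and Rhox9 from 10.26 ± 0.00 to 6.23 ± 0.62. The water channel gene Aqp3 fell by 3.23 and the kinesin gene Kif1a rose by 3.55 log2 units. In all 1145 features rose and 859 fell (4046 at an unadjusted p under 0.05), 759 and 650 of which had also risen and fallen with FGF4 and control shRNAs (68.6% and 59.1% of those calls; 89.8 and 66.9 from independent lists), and 0 were opposite. Simulations of unchanged groups shared 0 calls, but few features can pass there, so this does not measure what the shared arrays with no growth factor add, and part of the excess over independent lists may come from them. The count of 2004 was 4565 without shMP1G, and 740 and 737 without the shRnd1 and shRnd2 arrays with no growth factor.

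Of the lists, 11 passed camera with Mp1 shRNAs against no growth factor, 0 with an estimated correlation (lowest adjusted p = 0.0701 with an estimated correlation). Naive pluripotency gave 0 rises, 6 falls and 2 that did not pass, with 7 falls adjusted over the list alone: Dppa3 fell at least 4.17-fold, Klf4 by 2.41 and Tbx3 by 1.61 (list adjusted p = 4.7e-06; adjusted p = 0.0701 with an estimated correlation). The formative and primed epiblast list gave 6 rises and 3 that did not pass, with 6 adjusted over the list alone (adjusted p = 1.55e-06; adjusted p = 0.0701 with an estimated correlation). LIF/STAT3 targets gave 5 falls and 4 that did not pass, among them Socs3 (-2.90) and Rhox5 (-2.43), with 5 adjusted over the list alone (adjusted p = 0.000175; adjusted p = 0.125 with an estimated correlation). FGF/ERK genes gave 8 rises, 4 falls and 5 that did not pass, with 11 and 4 adjusted over the list alone, and Egr1 fell by 2.90 (adjusted p = 0.00906; adjusted p = 0.125 with an estimated correlation). Trophoblast genes gave 1 rise, 4 falls and 5 that did not pass, with 1 and 5 adjusted over the list alone (adjusted p = 0.0196; adjusted p = 0.272 with an estimated correlation), and surface ectoderm genes 6, 1 and 6, with 8 and 2 adjusted over the list alone (adjusted p = 0.0137; adjusted p = 0.125 with an estimated correlation), Msx1 rising by 2.49 and Krt8 by 1.88. The FGF/ERK call and those of trophoblast, surface ectoderm, glycolysis, Hox and epithelial to mesenchymal genes were lost without shMP1G (0.0513 each), as was that of cholesterol synthesis (0.113), and that of p53 targets without shMp1Lib (0.173).

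LIF, a cytokine that holds ES cells in self-renewal through STAT3, was compared with no growth factor in control shRNA cells. A single gene passed: Socs3, a direct STAT3 target, was lower on the arrays labelled LIF (7.65 ± 0.02, n = 2) than on those labelled no growth factor (11.03 ± 0.02, n = 2), a fall of 10.4-fold (adjusted p = 0.000651). It passed whichever array was left out. By limma 1035 features (7.34%) had an unadjusted p under 0.05. The nearest others did not pass: Lefty1 2.02 and the intermediate filament gene Ina at least 2.44-fold higher with LIF (Ina was not well above background without), and Igfbp7 -2.06 and Slit2 -1.18 lower (adjusted p = 0.0829, 0.0829, 0.0829 and 0.0935). Without either Mp1 shRNA array 19 features passed, among them Lefty1 and Ina (0.0303) and Igfbp7 (0.0106). Naive pluripotency genes did not pass (8 measured, list adjusted p = 0.306), and Klf4 stood at 10.00 ± 0.44 with LIF and 10.22 ± 0.19 without.

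Camera placed 7 lists apart between the arrays labelled LIF and no growth factor, 0 with an estimated correlation. LIF/STAT3 targets were lower (1 fell, 8 did not pass; 0 and 4 adjusted over the list alone; adjusted p = 7.17e-05), with Bcl3 at -1.49 (0.124), and so were FGF/ERK genes (0 past; 0 and 4 adjusted over the list alone; 0.0164), with Egr1 at -0.88 and Etv4 at -0.80, and cholesterol synthesis (0 past; 0.0164). BMP/SMAD targets (0 past; 5 and 0 adjusted over the list alone; 0.00108), formative genes (0 past; 3 and 0; 0.00561), general pluripotency (0 past; 1 and 0; 0.0093) and trophoblast genes (0 past; 3 and 0; 0.0315) were higher. The adjusted p was 0.145 with an estimated correlation for 6 of these lists and 0.383 for trophoblast. By fry the calls of trophoblast (adjusted p = 0.212) and cholesterol synthesis (0.0545) were lost, and against named features only that of trophoblast (0.0759). Without the shRnd2 array labelled LIF only the LIF/STAT3 call was left (general pluripotency and formative 0.154, trophoblast and FGF/ERK 0.185, BMP/SMAD 0.0607, cholesterol 0.191). Trophoblast and FGF/ERK also lost their calls without either Mp1 array (0.11), and trophoblast without the shRnd1 array with no factor (0.0679).

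FGF4 against LIF in control shRNA cells compared a differentiating with a self-renewing condition, by the labels. Car4 rose from 6.18 ± 0.42 with LIF to 11.94 ± 0.03 with FGF4 (n = 2 each; adjusted p = 1.76e-05), Slc40a1 at least 24.0-fold, Psmb8 at least 10.04-fold and Dusp4 from 5.74 ± 0.15 to 9.65 ± 0.08. Spic fell from 9.71 ± 0.04 to a level not well above background, at least 19.0-fold, Rhox9 from 10.94 ± 0.00 to 7.36 ± 0.25, and the urocanase gene Uroc1 and the meiotic kinase gene Aurkc at least 6.015-fold and 5.31-fold. In all 1124 features rose and 1088 fell (3959 at an unadjusted p under 0.05). Naive pluripotency gave 0 rises, 6 falls and 2 that did not pass (6 adjusted over the list alone; list adjusted p = 4.72e-05), formative genes 7, 0 and 2 (7 alone; 3.78e-08), FGF/ERK genes 8, 1 and 8 (12 and 2 alone; 4.42e-05) and cholesterol synthesis 8, 0 and 4 (9 alone; 6.11e-06), each with an adjusted p = 0.055 with an estimated correlation. Surface ectoderm genes gave 9 rises, 2 falls and 2 that did not pass (10 and 2 adjusted over the list alone; 0.000173; adjusted p = 0.0677 with an estimated correlation), and p53 targets 4, 0 and 13 (4 adjusted over the list alone; 0.00169; adjusted p = 0.33 with an estimated correlation). In the cholesterol list Dhcr7 rose by 1.56 and Idi1 by 1.39 (both detected on 1 of 2 LIF arrays). The calls of Hox genes (adjusted p = 0.0294), interferon response (0.0206) and epithelial to mesenchymal genes (0.0266) were lost without either Mp1 array (Hox, 0.0507), without the shRnd1 array with FGF4 (Hox, 0.0526) or without shRnd2 with LIF (0.0545 and 0.0676), and with an estimated correlation (adjusted p = 0.215, 0.214 and 0.196). LIF/STAT3 targets gave 1 rise, 3 falls and 5 that did not pass (3 and 3 adjusted over the list alone; median -0.10; list adjusted p = 0.835). The BMP/SMAD median was -0.20, its mean 0.39 and its camera direction up (adjusted p = 0.49). The count of 2212 was 981 and 987 without the shRnd1 and shRnd2 arrays with FGF4, 1133 without shRnd1 with LIF and 3325 without either Mp1 array. With scaling by array medians alone the median difference of all features was -0.11 here, against -0.01, and for Mp1 shRNAs against LIF it was -0.13, against 0.03.

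Mp1 knockdown in FGF4 against LIF gave 1564 rises and 1178 falls (5358 at an unadjusted p under 0.05). Car4 rose by 5.08 to 11.26 ± 0.19 (n = 2; adjusted p = 3.25e-05), Slc40a1 at least 21.0-fold, Etv4 from 6.43 ± 0.13 to 9.68 ± 0.07 and Vrtn at least 5.80-fold. Spic fell at least 20.5-fold, Rhox6 at least 16.1-fold and Rhox9 from 10.94 ± 0.00 to 6.23 ± 0.62. Naive pluripotency gave 0 rises, 6 falls and 2 that did not pass, 6 falls adjusted over the list alone (Klf2 -1.64, Dppa3 at least 4.52-fold lower; list adjusted p = 0.000229; adjusted p = 0.128 with an estimated correlation), and formative genes 6 rises and 3 that did not pass, 6 adjusted over the list alone (7.69e-05; adjusted p = 0.128 with an estimated correlation). Trophoblast genes gave 1 rise, 4 falls and 5 that did not pass, 1 and 4 adjusted over the list alone (0.0123; adjusted p = 0.265 with an estimated correlation, and 0.0647 without shMP1G). FGF/ERK genes gave 9 rises, 2 falls and 6 that did not pass (9 and 2 adjusted over the list alone; 0.00533; adjusted p = 0.13 with an estimated correlation) and cholesterol synthesis 7, 0 and 5 (8 adjusted over the list alone; 0.00255; adjusted p = 0.13 with an estimated correlation). LIF/STAT3 targets gave 0 rises, 3 falls and 6 that did not pass (2 and 3 adjusted over the list alone; 0.257). The calls of FGF/ERK genes and cholesterol synthesis, and those of surface ectoderm (0.0368) and Hox genes (0.0201), were lost without shMP1G (0.0647, 0.0724, 0.136 and 0.164), that of surface ectoderm also without shRnd2 with LIF (0.098), and that of p53 targets (0.0201) without shMp1Lib (0.0934). With an estimated correlation the last 3 lists had an adjusted p = 0.261, 0.261 and 0.458. The count of 2742 was 6082 without shMP1G, 1797 without either control array with FGF4, 893 without the shRnd1 array with LIF and 1700 without either array with no growth factor. When arrays were scaled by their medians 43.6% of the calls were higher, against 57.0%.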

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

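Restricting the tests to named or to listed features and the arrays labelled LIF as a baseline were chosen after seeing the data, and all other settings before. Over all settings 5730 of 6266 values of named genes kept their direction and side of the threshold, 504 no longer passed, 32 newly passed and 0 changed sign; for lists 589 of 689 kept both and 100 no longer passed. For genes, most of these losses came with 1 array left out. Signal over background limits what was tested: 14103 features passed the detection filter, 10440 when detection on all 8 arrays was asked, and 31336 without a filter. A block for chips was not run because the files name no chips, and gene lists on the deposited value table were not run because its IDs did not go with its values.

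With shRNA number as a replicate block the counts of changed features were 1 (Mp1 against control shRNA, 14 without the block), 1796 (FGF4 against no factor), 1 (LIF against no factor), 1704 (FGF4 against LIF), 1458 (Mp1 against no factor) and 1900 (Mp1 against LIF). The 1 feature in the first was Myl9 (adjusted p = 0.0338), while Cxcl16 (0.157) and Gap43 (0.162) did not pass and 0 of the 9 rises did. All 53 list calls and 312 of 338 named values kept their side of the threshold. Differences between shRnd1 and shRnd2 correlated between groups at -0.0832, -0.0696 and 0.043 across features. By the titles, same-numbered control samples carry the same shRNA vector, but the labels tie them to no shared culture or day, so they were not treated as pairs.

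For Mp1 against control shRNA the count of 14 (9 higher, 5 lower) became 2 with array medians (1 and 1), 53 with the deposited values (53 and 0), 0 with only the 4 arrays compared, 2 with array weights, 1 with listed features only, and 0 to 2841 with 1 array left out. The higher and lower counts were 9 and 2 without background correction or with an offset of 50, and 10 and 1 with detection on all arrays. For FGF4 against no factor (2205) it was 1385 with detection on all arrays, 3858 with the 4 arrays, 4112 with array weights and 1008 to 3232 with 1 array left out. With listed features only, 60.2% of its calls were higher. For LIF against no factor (1) it was 10 with the deposited values (1 higher, 9 lower), 3 without a detection filter, 33 with array weights and 1 to 19 with 1 array left out. For FGF4 against LIF (2212) it was 1388 with detection on all arrays and 981 to 3325 with 1 array left out. For Mp1 against no factor (2004) it was 1225 with detection on all arrays, 989 with the 4 arrays, 1323 with array weights and 737 to 4565 with 1 array left out. For Mp1 against LIF (2742) it was 702 with the 4 arrays, 1220 with array weights and 893 to 6082 with 1 array left out, and array medians gave 1147 higher and 1486 lower. Fewer arrays or features tested account for part of the smaller counts by construction. In comparisons without Mp1 arrays, leaving out either Mp1 array changed no compared value. Their larger counts in those fits come from a smaller pooled spread. For the rest the cause was not tested.

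The share of the FGF4 response left with Mp1 shRNAs (0.862 higher and 0.782 lower for features chosen on shRnd1, 0.861 and 0.808 on shRnd2) was 0.826 and 0.838 for lower features without background correction, 0.818 and 0.839 with an offset of 50, and 0.756 and 0.781 with detection on all arrays. With array medians it was 0.818 (lower, shRnd1), 0.815 (higher, shRnd2) and 0.882 (lower, shRnd2), and with the deposited values 1.03 and 1.08 (higher) and 0.808 (lower, shRnd1). The deposited values cover 42293 rows, against 45281 probes, and gave 53 rises and 0 falls for Mp1 against control shRNA. Which values are missing there was not tested, so these shares and that count may rest on an unlike set of features. Selection at 1.5-fold gave 0.828, 0.694, 0.905 and 0.777, and at 3-fold 0.841 and 0.884 for lower features. Against the arrays labelled LIF it was 0.957 and 0.843 (shRnd1) and 0.853 (lower, shRnd2). With 1 Mp1 array left out the ranges were 0.845 to 0.894, 0.785 to 0.795, 0.855 to 0.902 and 0.778 to 0.816. For the agreement of the 2 Mp1 shRNAs, same-numbered controls gave a correlation across features of 0.0819, and the deposited values one of -0.0453. The cause was not tested.

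Of 5, 13, 7, 9, 11 and 8 lists past the threshold (Mp1 against control, FGF4 and LIF against no factor, FGF4 against LIF, Mp1 against no factor and against LIF), 0 passed in each with an estimated correlation. These losses do not show that members vary together. For formative genes with Mp1 against control shRNA the estimated correlation was 0.0071, below the preset 0.01. Yet their adjusted p by camera went from 0.0119 to 0.174. Fry gave 5, 18, 5, 18, 18 and 15, and lost trophoblast and cholesterol synthesis for LIF against no factor (adjusted p = 0.212 and 0.0545). With 1 array left out the ranges were 0 to 7, 12 to 13, 1 to 8, 7 to 10, 4 to 11 and 3 to 9. With named features only 3, 11, 6, 9, 11 and 10 passed. The lost calls were formative genes and BMP/SMAD targets for Mp1 against control shRNA (0.0537 and 0.0786), general pluripotency and BMP/SMAD targets for FGF4 against no factor (0.0704 and 0.0673) and trophoblast for LIF against no factor (0.0759).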

Other observations

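Gene families were looked at after the data had been examined, and so were all tests of explanations given here. Rhox genes, an X-linked cluster of homeobox genes active in placenta and germ cells, were lower in all comparisons of FGF4 with cells kept without it: of 5 measured, 3 fell with FGF4 and control shRNA against no growth factor (median -1.21) and 5 fell with Mp1 shRNAs (median -2.43), with the same direction under every scaling tried. Claudins, which seal tight junctions, went the other way: of 7 measured, 5 rose with FGF4 and control shRNA (median 1.39; 4 when arrays were scaled by their medians) and 3 with Mp1 shRNAs (median 0.70; 2 when scaled by medians), and the medians were 0.78 and 0.35 without background correction. With Mp1 against control shRNAs, the direct test, 0 of the 5 Rhox genes and 0 of the 7 claudins passed with limma (medians -0.95 and -0.60, 2027 of all features at an unadjusted p under 0.05).

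Genes of interferon-inducible GTPases (Gbp and Irg families), which act against intracellular pathogens, were mostly higher with FGF4: of 6 measured, 4 rose with FGF4 and control shRNA (median 2.21) and 4 with Mp1 shRNAs (median 1.5), and the medians were 1.30 and 0.87 without background correction, with the same direction under every scaling tried. Of 16 genes of the H2 complex, which present peptides, 7 rose and 1 fell with FGF4 and control shRNA (median 0.36, and 0.27 without background correction), while with Mp1 shRNAs 4 rose and 2 fell (median -0.14, and -0.08 without background correction). Without background correction the H2 counts were 6 and 1 with control shRNA and 3 and 1 with Mp1 shRNAs. Scaled by array medians they were 6 and 0, and 2 and 1. With Mp1 against control shRNAs, 0 of these 6 and 0 of these 16 passed with limma (medians -0.40 and -0.41, 2027 of all features at an unadjusted p under 0.05), so neither family was shown to differ between the shRNAs.

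Named features were scarce among those higher with Mp1 shRNAs. The deposited value table, which gives the names, left out 94.7% of the 1660 features at least 0.5 log2 units higher, against 20.6% of all features, and 2220 of 2220 probes above a ratio of 1.28 between Mp1 and control shRNAs. A filter that removed probes above this ratio would leave few such rises among the table's values. Those values, whose IDs did not go with them, gave 53 rises and 0 falls for Mp1 against control shRNAs. The main fit gave 9 and 5. Whether the 53 rises lie above this ratio was not examined, and the fits used unlike sets of features. The counts therefore do not decide on such a filter, and why these IDs are missing stays unknown. Whether naive pluripotency genes are among the unnamed stayed open: of that list's 24 members 10 had no named probe and 8 were tested, so that 55.6% of these had no named probe, against 23.8% in the other lists counted the same way (75 without and 240 tested; Fisher's exact test, two-sided, p adjusted over 22 lists 0.112).

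Socs3 and other STAT3 targets were lower on the arrays labelled LIF, where LIF signals through STAT3, and with FGF4 the list fell against the arrays labelled no growth factor (camera, adjusted p = 0.00966) and did not pass against those labelled LIF (0.835), which rests on the same arrays. An exchange of the labels LIF and no growth factor may account for this. In a second list of LIF or STAT3 responsive genes, 8 of 12 measured were higher and 4 lower on the arrays labelled LIF, and adjusted over the list alone 1 passed, Irf1 (1.04 higher, adjusted p = 0.00814), which runs the way the labels say. The p-value of this list, fitted across all features with limma, was 0.498 by camera (direction up) and 0.0227 by fry (direction up), so an exchange stays open, as does a biological difference, which was not tested. The dimmer shRnd1 array labelled LIF was argued against as the source, since without it Socs3 still stood at -3.39 log2 units.

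The shMp1Lib array stood apart from shMP1G. Respiratory chain and ribosomal protein genes were lower on it by a median of -1.03 log2 units (156 of 187), against 0.160, 0.165 and 0.0056 between the arrays of the other groups, and by class by -1.57 for respiratory chain, -0.98 for mitochondrial ribosomal and -0.31 for cytosolic ribosomal protein genes. Lower yield of short abundant transcripts may be the source, or an effect of that shRNA, and with 1 array per Mp1 shRNA these cannot be told apart. Cytosolic ribosomal protein genes, which are short and abundant, moved least. How much less depended on the scaling. With array medians they stood at -0.79, against -1.01 for mitochondrial ribosomal protein and -1.81 for respiratory chain genes. A difference in how far the cells followed FGF4, taken as a median over features, was argued against, since the shares of the response left differed by at most 0.0491 between the shRNAs. Medians cannot show differences of single genes. Rbp7 stood at 7.91 with shMp1Lib and 9.57 with shMP1G, and Evx1 at 8.79 and 7.40.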
